A study of Mus musculus with 6 samples.

How the data were processed

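Poly-A RNA of purified splenic B cells, cultured for 6 h with anti-CD40, was sequenced on an Illumina HiSeq in 6 multiplexed libraries with 100 bp reads. The groups are 3 control (CD19-Cre) and 3 Nfkb2-deleted (floxed Nfkb2 with CD19-Cre) libraries. The file the authors deposited holds raw counts, whole numbers per gene symbol with no normalization. The labels name CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2 and the mouse build mm9. The counting tool, gene annotation, strand and treatment of reads with several matches are not given in the sources used here. Gapdh had 96 to 135 counts per library and Actb 84598 to 115719, so a gene with near-identical copies elsewhere may be undercounted. One part of the labels names floxed rel and added anti-IgM, while the titles, genotype and treatment fields name Nfkb2 and anti-CD40, which are used here. Whether the libraries of a group come from separate mice or separate cultures is not stated, so p-values measure only the spread between these samples.

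Of 23284 gene symbols 17840 had a count and 12026 passed edgeR's filterByExpr with a minimum count of 10 and were tested. The TMM factors, which scale libraries, ran from 0.988 to 1.01. Genes were tested two-sided with edgeR 4.0.16 (quasi-likelihood, TMM) in R 4.3.3 with Benjamini-Hochberg adjustment over the genes tested, and a gene passed, changed, rose or fell at an adjusted p under 0.05. Counts of genes before adjustment came to 3606 at a p under 0.05. The biological coefficient of variation was 4.84%. CPM are counts scaled by library totals and TMM. The counting interval of a ratio covers counting error only. In the file 25 names had the form of a date and are not named here, and 2 of them passed.

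The groups, test, gene lists and rule for named genes were fixed before the data were examined. The test planned for normalized values was limma on a log scale, with edgeR named for a file of counts, and alternatives worded for FPKM were run on CPM. Named were the 5 NF-kB subunit genes, the 12 genes with the largest rise and the 12 with the largest fall among those that passed with groups that did not overlap, and up to 4 members of each list with the smallest p. Genes outside this rule, among them members of lists where 5 or fewer passed in a direction, and genes of at least 50 CPM on no list, were chosen after their values were seen.

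The 46 lists hold 1112 members, of which 1085 matched by symbol, 7 by another name and 4 by a RefSeq synonym, and 16 were not found. Camera in limma 3.58.1 tested the 43 lists with at least 5 measured members, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives. The lists cover NF-kB, B cell signalling and subsets, survival, cell cycle, growth, metabolism, stress, interferon and antigen presentation, Notch and TGF-beta, markers of other cell types, sex-linked and histone genes, and genes beside Nfkb2. A reference for mm9 was not available, so GRCm38 served for names and neighbours and no coordinates are given.

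Tested on simulated data with 12026 genes, the same steps recovered 36 of 67 genes (53.7%) at the smallest change put in, where the median measured log2 fold was 0.30, 49 of 67 genes changed 1.5-fold and 58 of 66 changed 2-fold, while the median size in the genes that changed was 0.27, and 15 of 158 calls were false (9.49%). With no change put in, 0 lists and 1 gene were called. Genes were simulated independently of each other, so the 0 does not give a false-call rate for lists whose genes move together. In the data the estimated correlation reached 0.577, in the oxidative phosphorylation list. Alternatives included DESeq2 1.42.0, other filters, scalings, pseudocounts and variance settings, a replicate block and leaving out each library in turn. Residuals of equal replicate numbers correlated at 0.038, −0.007 and −0.095 across genes, which are not independent replicates, so samples were not paired. Control 3 and deleted 2 correlated at 0.184, the highest value across the groups. The replicate block, which joins equal numbers, does not cover that pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.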

Results

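RNA was sequenced from splenic B cells of littermate mice aged 12 weeks. The cells had been purified with magnetic beads and cultured for 6 h with antibodies against CD40, the receptor through which T cells activate B cells. The control group carried CD19-Cre, a recombinase expressed in the B lineage, and the other group also carried floxed alleles of Nfkb2 (called Nfkb2-deleted here). Each group had 3 libraries, called control 1 to 3 and deleted 1 to 3. The libraries held 17769022, 18240954 and 19239980 counts in the control group and 22740452, 19927434 and 23691890 in the Nfkb2-deleted group. A count was present for 16273, 14696 and 14720 genes in the controls, and for 15197, 15100 and 15331 genes in the Nfkb2-deleted libraries. The comparison asks how the transcripts of CD40-stimulated B cells differ when Nfkb2 is deleted. Levels are counts scaled to a common library size (CPM), and log2 fold changes are Nfkb2-deleted over control with an SE. This SE is the size of the log2 fold change divided by the square root of the F statistic of the edgeR test. It can fall short of the counting error in genes with few counts in a group.

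Nfkb2 encodes the precursor of the NF-kB subunit that acts with RelB in the alternative NF-kB pathway. Its transcripts fell from 927 ± 11.9 CPM in the controls to 288 ± 7.81 CPM in the Nfkb2-deleted group (SD, n = 3 each), 31.0% of the control level. The log2 fold change was −1.69 ± 0.03, with an edgeR adjusted p = 1.6e-09, and all 3 Nfkb2-deleted libraries lay below all 3 controls. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give. Nfkb1, which encodes a subunit of the classical pathway, rose by 0.16 ± 0.03 on the log2 scale (edgeR adjusted p = 3.5e-03). Rel, which encodes c-Rel, changed by −0.26 ± 0.05 (edgeR adjusted p = 4.9e-03). Rela at 0.01 ± 0.04 and Relb at 0.03 ± 0.03 did not pass (edgeR adjusted p = 0.902 and 0.620). Counts are per gene and include any exon outside the floxed part, and which exons were floxed is not given in the sources used here.

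**Figure D1:**
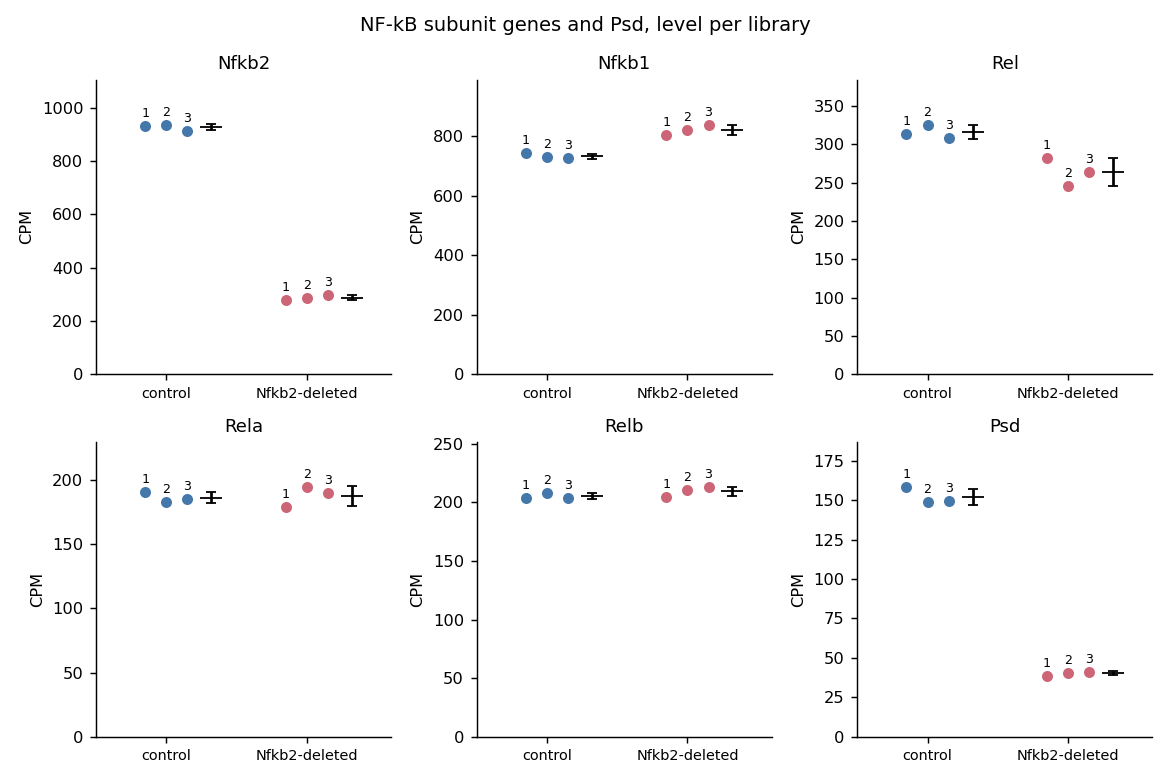
CPM of the 5 NF-kB subunit genes and of Psd in each library. Points are libraries, numbered by replicate, and black marks are the group mean with SD (n = 3), with Nfkb2 near 927 CPM in the controls and 288 CPM in the Nfkb2-deleted libraries and Psd near 152 and 40.2 CPM.

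Some genes beside Nfkb2 on chromosome 19 fell too. Psd, an exchange factor for small GTPases, fell from 152 ± 5.24 to 40.2 ± 1.32 CPM (SD, n = 3 each), with a log2 fold change of −1.92 ± 0.04 (edgeR adjusted p = 3.5e-09). Fbxl15, the next gene, changed by −0.72 ± 0.12 (edgeR adjusted p = 2.0e-03). Gbf1 on the other side of Nfkb2, at −0.04 ± 0.04, and Cuedc2 beyond Fbxl15, at 0.01 ± 0.04, did not pass (edgeR adjusted p = 0.636 and 0.879). Of 19 measured genes around the locus, 0 rose and 4 fell (0 and 4 adjusted over the list alone), the others being Nolc1 at −0.26 and Pprc1 at −0.21. Camera placed the list lower (adjusted p = 2.2e-05), also with an estimated correlation (camera adjusted p = 0.0492). Nolc1 also stands on the ribosome biogenesis list. The list of genes around the locus had a median of −0.05 and a mean of −0.17, and it was not tested without Psd. With quantile normalization, which here and below was run in limma with 1 CPM added, it no longer passed (camera adjusted p = 0.0553, range over its alternatives 6.5e-07 to 0.0553). In the GRCm38 annotation Psd overlaps Nfkb2 on the opposite strand, and whether counting respected strand is not stated, so reads of this pair cannot be told apart.

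Across the transcriptome, 2111 of 12026 genes tested changed, with 1279 higher and 832 lower in the Nfkb2-deleted group (edgeR with Benjamini-Hochberg adjustment). Most large changes were rises: a log2 fold of at least 1 was reached by 320 genes that rose and by 16 that fell, and 87.5% of those large rises were in genes below 10 CPM. Among the 8602 genes at 10 CPM or more, 831 rose and 789 fell. In 2108 of the 2111 changed genes the libraries of the groups did not overlap, nor did they in 4115 of all genes tested, where chance gives 10%. The higher share of the changed genes was 60.6%, and it depended on scaling: it was 70.8% of 2032 changed genes when libraries were scaled by totals alone, and 53.1% of 2256 (1197 higher and 1059 lower) in limma with 1 CPM added and median centring. Limma with 1 CPM added gave 61.1% without that centring and 57.8% with quantile normalization. Leaving out control 2 gave 1341 changed genes and leaving out deleted 3 gave 1228. The number lower was 418, 528 and 403 without control 2, control 3 or deleted 3, and 825 were higher without deleted 3. Without those same libraries, 30, 30 and 10 genes fell with a log2 fold of at least 1.

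**Figure D2:**
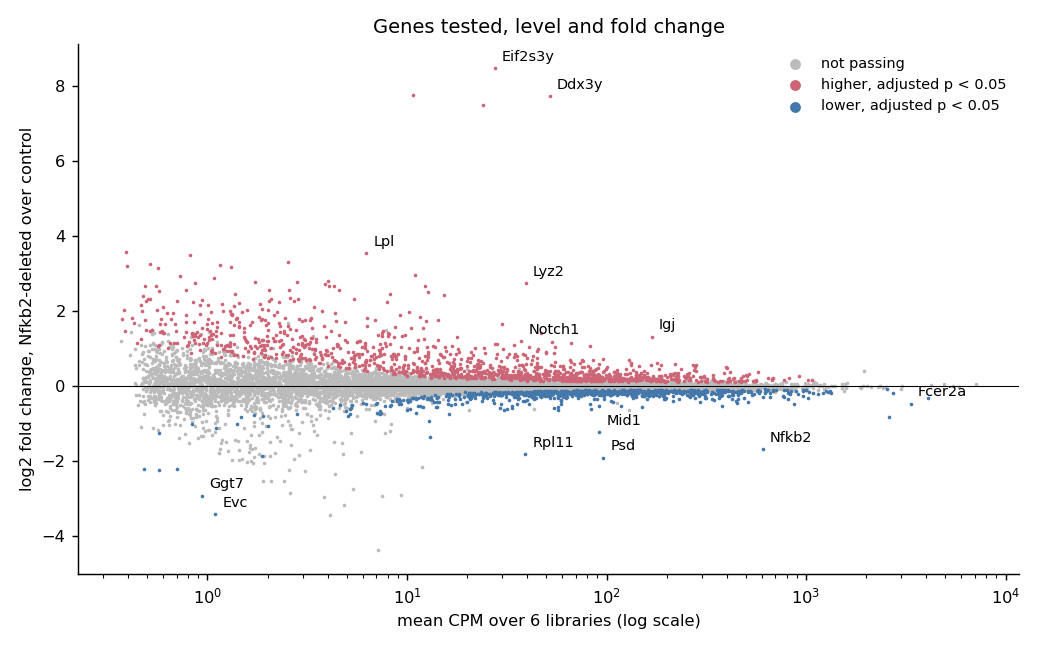
Mean CPM over the 6 libraries (log axis) against log2 fold change, Nfkb2-deleted over control, for the 12026 genes tested. Each point is a gene, with the 1279 genes that rose in red, the 832 that fell in blue and those not passing in grey, and Eif2s3y at the top at 8.49.

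The 4 largest rises were Y-linked: Eif2s3y at 8.49 ± 0.23, Uty at 7.77 ± 0.26, Ddx3y at 7.75 ± 0.18 and Kdm5d at 7.51 ± 0.17. In the control group these genes had 8, 5, 26 and 14 counts, so their SE can fall short of the counting error. Summed, these genes reached 236, 227 and 219.6 CPM in the Nfkb2-deleted libraries and 2.04, 0.663 and 0.263 CPM in the controls. Xist, the RNA of the inactive X chromosome, fell from 3324 ± 225 to 1865 ± 220.1 CPM (SD, n = 3 each), a log2 fold change of −0.83 ± 0.08 (edgeR adjusted p = 5.5e-05). All 5 measured members of the sex-linked list passed, 4 higher and 1 lower (4 and 1 adjusted over the list alone), and camera placed it higher (adjusted p = 2.0e-157, or 4.2e-03 with an estimated correlation). The groups thus differed in sex-linked transcripts in the same libraries as in every other result given here. Without control 1, the log2 fold change of Eif2s3y was 10.70, and 7.90 without control 3. Without control 1, the log2 fold change of Uty was 8.47. Without control 1, the log2 fold change of Ddx3y was 9.05.

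The next 8 largest rises were in genes of low level. Lpl, lipoprotein lipase, rose from 0.992 ± 0.424 to 11.5 ± 0.532 CPM (SD, n = 3 each), a log2 fold change of 3.54 ± 0.21. F13a1, a coagulation factor subunit, rose by 3.32 ± 0.30, Msr1, a macrophage scavenger receptor, by 3.18 ± 0.33, and Kel, a blood group protein of red cells, by 3.49 ± 0.42. Gpr141 at 3.22 ± 0.32, Abca9 at 3.26 ± 0.44 and Cldn13 at 3.19 ± 0.57 also rose. Kel, Abca9 and Cldn13 had 7, 5 and 4 counts in the control group, where the same limit of the SE holds. Loxl2 had 3 counts in the control group and 48 in the Nfkb2-deleted group, a ratio of 13.3 with a 95% counting interval of 4.29 to 66.9. The highest adjusted p among these 8 genes was that of Cldn13 (edgeR adjusted p = 3.7e-03). Without control 1, the log2 fold change of Abca9 was 3.96. Without control 3, the log2 fold change of Cldn13 was 4.41. Without control 2, the log2 fold change of Loxl2 was 4.44.

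Besides Nfkb2 and Psd, the largest falls included Mid1, a ubiquitin ligase bound to microtubules. Mid1 fell from 129 ± 1.52 to 55.1 ± 3.36 CPM (SD, n = 3 each), a log2 fold change of −1.23 ± 0.05 (edgeR adjusted p = 1.6e-07). The groups differed in sex-linked transcripts too, so whether Mid1 fell with Nfkb2 or with sex cannot be told apart. Rpl11, a ribosomal protein gene, changed by −1.82 ± 0.09, a value that is uncertain because copies elsewhere in the genome can take its reads. Evc changed by −3.42 ± 0.58, Gm600 by −2.25 ± 0.42, Trp73 by −2.21 ± 0.42 and Pde1c by −1.89 ± 0.23 (edgeR adjusted p = 2.8e-03, 4.7e-03, 5.4e-03 and 3.4e-04). Ggt7 at −2.93 ± 0.79 and Gnaz at −2.23 ± 0.55 fell as well. So did counts at the entries of the small nucleolar RNAs Snora62, at −1.27 ± 0.31, and Snord57, at −1.13 ± 0.26. Whether these poly-A reads came from the small RNAs themselves was not tested. Without deleted 3, the log2 fold change of Evc was −2.81. Ggt7 did not pass without deleted 1, deleted 2 or deleted 3 (edgeR adjusted p = 0.108, 0.0542 and 0.105), with 10 of 18 alternatives passing and a range of 6.5e-04 to 0.138. Without control 1, the log2 fold change of Ggt7 was −1.54. Gnaz did not pass without deleted 1 or deleted 3 (edgeR adjusted p = 0.0775 and 0.103), with 15 of 18 alternatives passing and a range of 7.8e-03 to 0.103. The log2 fold change of Gnaz was −2.91 without deleted 2 and −1.68 without control 1. That of Trp73 was −1.88 without control 1. Among the controls, control 1 had the most counts of Ggt7, Gnaz and Trp73, at 66, 34 and 20. Control 1 also held nervous tissue transcripts, described below. Snora62 did not pass without control 2, deleted 1 or deleted 3 (edgeR adjusted p = 0.0789, 0.0758 and 0.0922), with 12 of 18 alternatives passing and a range of 0.0172 to 0.174. Snord57 did not pass without control 3 or deleted 1 (edgeR adjusted p = 0.0572 and 0.0640), with 14 of 18 alternatives passing and a range of 8.0e-03 to 0.0664.

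Some markers of other blood cells rose in the Nfkb2-deleted libraries, although the cells had been purified as B cells. Of 15 measured macrophage and monocyte markers, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 1.53. Lyz2, lysozyme, rose from 10.2 ± 0.315 to 68.7 ± 5.05 CPM (SD, n = 3 each), and Csf1r, the receptor of macrophage colony-stimulating factor, by 2.50 ± 0.11. Camera placed this list higher (adjusted p = 2.2e-31, or 4.7e-03 with an estimated correlation). Of 14 neutrophil markers, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with Csf3r at 1.76 ± 0.11 and S100a8 at 1.33 ± 0.11, median 1.35 (camera adjusted p = 6.7e-12, or 0.0357 with an estimated correlation). Of 11 erythroid markers, 7 rose and 0 fell (7 and 2 adjusted over the list alone), with the anion exchanger Slc4a1 at 2.25 ± 0.12 and Gypa at 2.04 ± 0.27, median 1.37 (camera adjusted p = 4.1e-05, or 0.0492 with an estimated correlation). The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 had 0 counts in all 6 libraries, which does not show that they were absent, because these genes have near-identical copies and whether reads with several matches were counted is not stated.

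Of 11 NK cell markers, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with Klrd1 at 1.26 ± 0.19 and Klrk1 at 1.42 ± 0.24, median 1.16 (camera adjusted p = 8.2e-04, but adjusted p = 0.0649 with an estimated correlation). Of 22 T cell markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with Tcf7 at 0.65 ± 0.06 and Lck at 0.40 ± 0.06, median 0.44 (camera adjusted p = 0.0123, but adjusted p = 0.0980 with an estimated correlation). Of 13 dendritic cell markers, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Itgax at 1.59 ± 0.15 and Siglech at 1.93 ± 0.26, median 0.82 (camera adjusted p = 2.1e-03, but adjusted p = 0.0770 with an estimated correlation). The dendritic cell list did not pass among genes of at least 10 CPM without control 1 (camera adjusted p = 0.323, range over its alternatives 4.9e-04 to 0.323). Of 5 platelet markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone), namely Thbs1 at 2.77 ± 0.19 and Ppbp at 1.34 ± 0.33 (camera adjusted p = 0.0312, but adjusted p = 0.138 with an estimated correlation). The platelet list did not pass without deleted 1 or deleted 2 (camera adjusted p = 0.0680 and 0.0652, range 9.0e-04 to 0.138). The basophil and stromal lists, with 2 and 3 measured members, were too small for camera. Kit at 1.02 ± 0.17 and Hdc at 1.15 ± 0.33 rose in the former (2 and 0 adjusted over the list alone), and Pecam1 at 0.30 ± 0.04 in the latter (1 and 0 adjusted over the list alone). Ppbp did not pass without control 2, deleted 1, deleted 2 or deleted 3 (edgeR adjusted p = 0.0825, 0.0570, 0.0678 and 0.0638), with 11 of 18 alternatives passing and a range of 0.0111 to 0.0825. Hdc did not pass with any 1 library left out (edgeR adjusted p = 0.0818 to 0.142), with 4 of 18 alternatives passing and a range of 0.0323 to 0.451.

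Control 1 differed from the other libraries in another way. It held 714 genes at 10 times or more the level of every other library, with 0.276% of its counts, and the other 5 libraries held 0 such genes. Snap25, a synaptic protein of neurons, had 953 counts in control 1 and at most 1 count in any other library. Without control 1, 2335 genes changed, and 1846 of these were among the 2111.

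**Figure D3:**
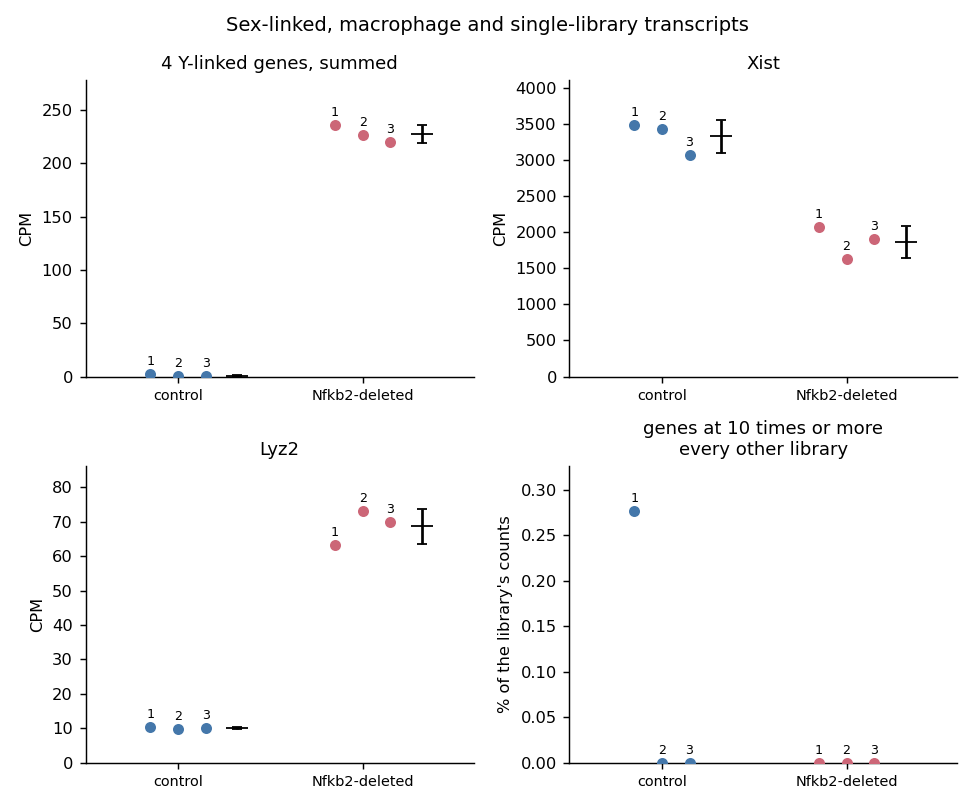
Level per library of the 4 Y-linked genes summed, Xist and Lyz2 (CPM), and the percent of counts in genes at 10 times or more the level of every other library, with points numbered by replicate and black marks for the group mean with SD (n = 3). The Y-linked sum was at most 2.04 CPM in a control and at least 219.6 CPM in a Nfkb2-deleted library, and the percent was 0.276 in control 1 and 0 elsewhere.

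Of 43 gene lists tested with camera, 29 passed, 20 higher and 9 lower, or 8 lower with Nfkb2 left out of the list that holds it. With an estimated correlation 9 passed: sex-linked genes, macrophage, neutrophil and erythroid markers, B-1, marginal zone and plasma cell genes, cholesterol synthesis genes and genes beside Nfkb2. Regroupings of the 6 libraries that mixed the groups gave 7 to 19 lists at the preset correlation.

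**Figure D4:**
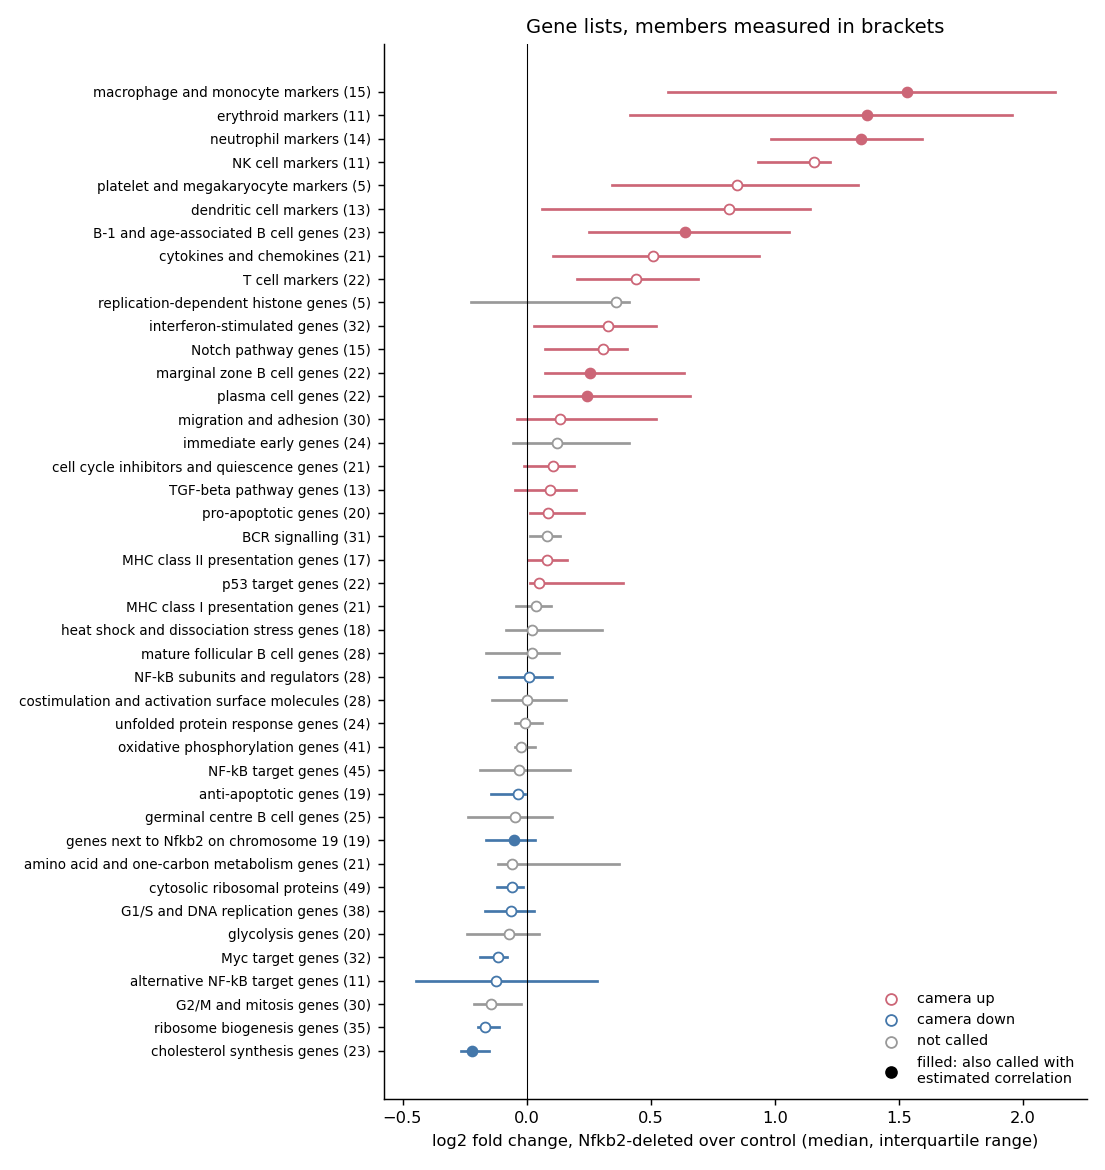
Median (circle) and interquartile range (line) of the log2 fold change, Nfkb2-deleted over control, over the measured members of each tested list except the sex-linked list, with their number in brackets. Red and blue mark lists camera placed higher and lower, grey those not passing, and filled circles those also passing with an estimated correlation, with macrophage markers at 1.53 and cholesterol synthesis genes at −0.22.

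Of 11 measured targets of the alternative NF-kB pathway, 1 rose and 5 fell (2 and 6 adjusted over the list alone), and camera placed the list lower (adjusted p = 5.9e-05, but adjusted p = 0.0649 with an estimated correlation). Fcer2a, which encodes the low-affinity IgE receptor CD23, fell from 3887 ± 14.8 to 2797 ± 21.3 CPM (SD, n = 3 each), a log2 fold change of −0.47 ± 0.02 (edgeR adjusted p = 1.1e-06). Cr2, complement receptor CD21, changed by −0.55 ± 0.04, Bcl2l1, which encodes the survival protein Bcl-xL, by −0.42 ± 0.04, the chemokine receptor gene Ccr7 by −0.28 ± 0.04 and Cxcr5 by −0.12. Il12b, a cytokine subunit gene, rose by 0.63. Cxcr5 did not pass without control 2, control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.105, 0.135, 0.0901 and 0.140), with 10 of 20 alternatives passing and a range of 5.1e-03 to 0.286.

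The wider list of 45 NF-kB targets moved both ways: 10 rose and 16 fell (12 and 17 adjusted over the list alone). The chemokine gene Ccl22 rose from 73.0 ± 1.15 to 119.8 ± 4.63 CPM (SD, n = 3 each), and Cd86, a costimulatory ligand, by 0.48 ± 0.04. Ebi3, a cytokine subunit, changed by −0.56 ± 0.04. Of its 26 changed members 1 also stands on a list of another cell type. Camera did not place this list (adjusted p = 0.252, direction down, median −0.03, mean 0.08), and it passed as lower without deleted 2 (camera adjusted p = 0.0297, range 0.0297 to 0.936). Of 28 NF-kB subunits and regulators, 5 rose and 6 fell (9 and 8 adjusted over the list alone). The rises were Nfkb1, Tnip1 at 0.24, Nfkbid at 0.23, Nfkbie at 0.19 and Traf3 at 0.18. Nfkb2 itself is a member, and with it camera placed the list lower (adjusted p = 0.0376, but adjusted p = 0.141 with an estimated correlation), at a median of 0.01 and a mean of −0.05. The 27 other members did not pass and their direction was up (camera adjusted p = 0.819, median 0.01, mean 0.01), so the lower call rested on the deleted gene. With Nfkb2 kept, it did not pass without control 2 either (camera adjusted p = 0.0575), and its direction was up with quantile normalization. It passed in 10 of 22 alternatives, with a range of 1.9e-03 to 0.927. Traf3 did not pass without control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.0629, 0.0538 and 0.0773), with 17 of 20 alternatives passing and a range of 1.8e-03 to 0.0773.

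Of 22 marginal zone genes, 12 rose and 3 fell (14 and 3 adjusted over the list alone), with Asb2 rising from 14.5 ± 1.33 to 45.4 ± 1.79 CPM (SD, n = 3 each) and the tetraspanin gene Cd9 by 0.88 ± 0.05. The falls were Ebi3 at −0.56, Cr2 at −0.55 and Cd1d1 at −0.19. Of 23 B-1 and age-associated B cell genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone), with Ahnak at 1.42 ± 0.08 and Zbtb32 at 1.08 ± 0.06 among the rises and with Zcwpw1 at −0.15 and Nid1 at −0.11 as the falls. Of its 16 changed members 3 also stand on lists of other cell types, and the macrophage list had a median of 1.53. Without control 1 it had 0 members that fell. Of 22 plasma cell genes, 12 rose and 2 fell (14 and 3 adjusted over the list alone), and 2 of its 14 changed members stand on lists of other cell types. Igj, the joining chain of secreted antibody, rose from 96.8 ± 8.56 to 241 ± 12.8 CPM (SD, n = 3 each) and Prdm1, the transcription factor Blimp-1, by 0.77 ± 0.07. Irf4, a transcription factor of activated B cells, fell at −0.28 ± 0.03, as did Slamf7 at −0.31 ± 0.04. Camera placed all 3 lists higher (adjusted p = 2.5e-09, 5.2e-20 and 7.0e-05), also with an estimated correlation (camera adjusted p = 0.0251, 0.0134 and 0.0492). Cd1d1 did not pass without control 2, control 3, deleted 2 or deleted 3 (edgeR adjusted p = 0.0937, 0.0959, 0.0536 and 0.0932), with 14 of 20 alternatives passing and a range of 0.0173 to 0.137. Zcwpw1 did not pass with any 1 library left out (edgeR adjusted p = 0.0694 to 0.120), with 3 of 20 alternatives passing and a range of 0.0365 to 0.283. Nid1 did not pass with any 1 library left out (edgeR adjusted p = 0.0709 to 0.116), with 8 of 20 alternatives passing and a range of 0.0220 to 0.147.

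Of 28 mature follicular genes, 7 rose and 9 fell (10 and 11 adjusted over the list alone). Besides Fcer2a and Cr2, which fell, Fcrla rose by 0.43 ± 0.04 and Klf2, a transcription factor of resting lymphocytes, by 0.52 ± 0.06. No direction was called for the list (camera adjusted p = 0.614, direction down, median 0.02, mean 0.0026). Of 25 germinal centre genes, 3 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.596). The repressor gene Bcl6 changed by −0.26 ± 0.03, Lmo2 by −0.48 ± 0.06, Mef2c by −0.24, Mybl1 by −0.81 and Gm600, also called Nuggc, by −2.25. Fcrl5 at 0.68, Bach2 at 0.35 and Myb at 0.22 rose. None of the immunoglobulin constant region genes on their list was found in the file by name. Myb did not pass without deleted 3 (edgeR adjusted p = 0.0575), with 19 of 20 alternatives passing and a range of 1.5e-03 to 0.0575.

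Of 21 cytokines and chemokines, 10 rose and 3 fell (14 and 3 adjusted over the list alone), with Ccl22 at 0.72 ± 0.04 and Cxcl16 at 1.04 ± 0.11 among the rises, and Ebi3 at −0.56, Lta at −0.54 ± 0.05 and Tnf at −0.36 ± 0.07 as the falls. The list was placed higher (camera adjusted p = 6.4e-03, but adjusted p = 0.0997 with an estimated correlation), and 2 of its 13 changed members stand on lists of other cell types. It did not pass among genes of at least 10 CPM without control 1 (camera adjusted p = 0.180, range 1.3e-04 to 0.180). Of 30 migration and adhesion genes, 13 rose and 5 fell (17 and 7 adjusted over the list alone). The chemokine receptor genes Cxcr7 and Cxcr4 rose by 1.54 ± 0.09 and 0.57 ± 0.04, S1pr1, the receptor used to leave lymphoid tissue, by 0.79 ± 0.05 and Rgs2 by 0.76 ± 0.05. Gpr183 at −0.43 ± 0.04, Ccr7 at −0.28, Icam1 at −0.14, Itgal at −0.14 and Cxcr5 at −0.12 fell. This list too was placed higher (camera adjusted p = 3.0e-06, but adjusted p = 0.0885 with an estimated correlation). Icam1 did not pass without control 2 (edgeR adjusted p = 0.0602), with 19 of 20 alternatives passing and a range of 7.8e-04 to 0.0602. Itgal did not pass without control 2 or control 3 (edgeR adjusted p = 0.0671 and 0.0583), with 16 of 20 alternatives passing and a range of 1.5e-03 to 0.0728. Cxcr5 did not pass without control 2, control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.105, 0.135, 0.0901 and 0.140), with 10 of 20 alternatives passing and a range of 5.1e-03 to 0.286.

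Of 28 costimulation and activation molecules, 6 rose and 10 fell (7 and 12 adjusted over the list alone), with Cd86 and Cd80, at 0.60 ± 0.06, among the rises and Ly9, at −0.28 ± 0.03, among the falls. No direction was called (camera adjusted p = 0.270, direction down, median 0.0011, mean 0.04). Of 31 B cell receptor signalling genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone). The inhibitory receptor genes Cd72 at 0.27 ± 0.03 and Siglecg at 0.29 ± 0.03 and the kinase gene Blk at 0.25 ± 0.03 rose, and Cr2 at −0.55, Cd19 at −0.19 and Pik3cd at −0.16 fell. The list did not pass (camera adjusted p = 0.0528), but did without deleted 2 (camera adjusted p = 9.9e-03, with 10 of 21 alternatives passing and a range of 1.8e-04 to 0.477). Of 24 immediate early genes, 7 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.216, with 5 of 21 alternatives passing and a range of 0.0174 to 0.830). Atf3 rose from 2.07 ± 0.383 to 4.92 ± 0.465 CPM (SD, n = 3 each) and the antiproliferative gene Btg2 by 0.44 ± 0.04, whereas Myc changed by −0.32 ± 0.04, Jun by −0.35 ± 0.05 and Jund by −0.27. Cd19 did not pass with quantile normalization (limma adjusted p = 0.0777), with 19 of 20 alternatives passing and a range of 9.6e-08 to 0.0777. Jund did not pass without deleted 3 (edgeR adjusted p = 0.0537), with 19 of 20 alternatives passing and a range of 1.9e-05 to 0.0537.

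Of 19 anti-apoptotic genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone), with Bcl2l1 falling from 124 ± 1.69 to 92.7 ± 2.32 CPM (SD, n = 3 each), the kinase gene Pim3 at −0.32 ± 0.05, and rises of Pim2 at 0.20 and Gadd45b at 0.17. The list was placed lower (camera adjusted p = 0.0352, but adjusted p = 0.138 with an estimated correlation), in 15 of its 21 alternatives with a range of 4.1e-03 to 0.188. Of 20 pro-apoptotic genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). Bmf, which encodes a protein that opposes Bcl-2 family survival proteins, rose from 41.1 ± 0.768 to 91.5 ± 4.14 CPM (SD, n = 3 each), Trp53inp1 by 0.53 ± 0.04 and Bbc3, which encodes Puma, by 0.28 ± 0.05, and Bcl2l11 at −0.13 fell. Camera called it higher (adjusted p = 3.3e-04, but adjusted p = 0.0997 with an estimated correlation), with 0 members that fell without control 1. Pim2 did not pass without control 2 or deleted 3 (edgeR adjusted p = 0.0570 and 0.0659), with 18 of 20 alternatives passing and a range of 1.9e-03 to 0.0659. Gadd45b did not pass without control 2, control 3, deleted 2 or deleted 3 (edgeR adjusted p = 0.0728, 0.122, 0.0680 and 0.0689), with 15 of 20 alternatives passing and a range of 0.0175 to 0.122. Bcl2l11 did not pass with any 1 library left out (edgeR adjusted p = 0.0542 to 0.0991), with 10 of 20 alternatives passing and a range of 0.0139 to 0.128.

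Of 38 genes of G1/S and DNA replication, 3 rose and 9 fell (3 and 10 adjusted over the list alone), with the cyclin gene Ccnd2 falling from 479 ± 4.43 to 373 ± 3.10 CPM (SD, n = 3 each) and Mcm5, a subunit of the replicative helicase, at −0.28 ± 0.04. E2f2 at 0.34, Ccnd1 at 0.69 and Ccnd3 at 0.26 rose. The list was called lower (camera adjusted p = 0.0429, but adjusted p = 0.141 with an estimated correlation), and not without control 3, deleted 1 or deleted 2 (camera adjusted p = 0.080, 0.0608 and 0.0537, range 5.9e-03 to 0.141). Of 21 cell cycle inhibitor and quiescence genes, 9 rose and 0 fell (11 and 1 adjusted over the list alone), with Cdkn1a, the inhibitor p21, at 0.73 ± 0.08 and Ccng2 at 0.38 ± 0.04 (camera adjusted p = 8.2e-04, but adjusted p = 0.0649 with an estimated correlation). Of 30 G2/M genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), namely Cenpe, a mitotic motor protein, at −0.31 ± 0.09, and 2 fell without control 1. That list did not pass (camera adjusted p = 0.123), but did without control 2 (camera adjusted p = 0.0371, with 6 of 21 alternatives passing and a range of 1.3e-03 to 0.627). Of 25 replication-dependent histone genes on their list, only 5 were measured in these poly-A libraries. Of those, Hist1h1c rose by 0.62 (1 and 0 adjusted over the list alone, with a camera adjusted p = 0.591). The measured 5 do not describe these histone genes as a whole. Ccnd3 did not pass without control 2 or deleted 3 (edgeR adjusted p = 0.0622 and 0.0689), with 18 of 20 alternatives passing and a range of 7.3e-03 to 0.0689. Cenpe did not pass without control 3, deleted 1, deleted 2 or deleted 3 (edgeR adjusted p = 0.131, 0.0756, 0.0694 and 0.146), with 12 of 20 alternatives passing and a range of 0.0217 to 0.146.

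Of 35 ribosome biogenesis genes, 0 rose and 22 fell (0 and 26 adjusted over the list alone), with Gnl3 at −0.26 ± 0.03, Nop56 at −0.22 ± 0.03 and Wdr43 at −0.21 ± 0.03. The list was called lower (camera adjusted p = 3.7e-11, but adjusted p = 0.0649 with an estimated correlation). Of 32 Myc targets, 0 rose and 12 fell (0 and 19 adjusted over the list alone), with Myc itself falling from 221 ± 3.81 to 177 ± 7.56 CPM (SD, n = 3 each), the hexokinase gene Hk2 at −0.31 ± 0.04 and the nucleolin gene Ncl at −0.19 ± 0.03, which was at 0.02 with quantile normalization. Camera called the list lower (adjusted p = 1.0e-06, but adjusted p = 0.282 with an estimated correlation). Of 49 cytosolic ribosomal protein genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone), namely Rpl11 at −1.82, Rpl10 at −0.29, Rps12 at −0.29, Rpl10a at −0.26 and Rpl7 at −0.14, and 10 fell without control 1. Their list was lower too (camera adjusted p = 1.4e-03, but adjusted p = 0.601 with an estimated correlation), though not with quantile normalization or in fry (adjusted p = 0.107 and 0.190, range 2.1e-07 to 0.601). Counts of these genes are uncertain because near-identical copies share their reads. Ncl did not pass with quantile normalization (limma adjusted p = 0.760). Nor did it pass among genes of at least 10 CPM without control 1 (edgeR adjusted p = 0.0552). Ncl passed in 18 of 20 alternatives, with a range of 8.2e-10 to 0.760. Rpl7 did not pass without control 3 or deleted 3 (edgeR adjusted p = 0.0679 and 0.0768), with 16 of 20 alternatives passing and a range of 7.5e-04 to 0.151.

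Of 23 cholesterol synthesis genes, 0 rose and 17 fell (0 and 18 adjusted over the list alone). Insig1, which restrains sterol synthesis, fell from 246 ± 2.45 to 185 ± 0.826 CPM (SD, n = 3 each), the LDL receptor gene Ldlr changed by −0.32 ± 0.03, and the synthesis enzymes Lss and Cyp51 by −0.31 ± 0.04 and −0.23 ± 0.03. Camera called the list lower (adjusted p = 2.6e-12, or 0.0492 with an estimated correlation). Of 20 glycolysis genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.492). Pfkfb3 at 0.36, Slc16a3 at 1.35 and Pfkp at 0.13 rose, and Hk2 at −0.31, Slc16a1 at −0.28, Slc2a3 at −0.26 and Pdk1 at −0.16 fell. Of 41 oxidative phosphorylation genes 0 passed in edgeR (0 and 0 adjusted over the list alone), and 2 had an unadjusted p under 0.05. That list did not pass (camera adjusted p = 0.504), but did without deleted 2 (camera adjusted p = 0.0449, range 0.0449 to 0.998). Pfkp did not pass without control 2, control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.121, 0.133, 0.117 and 0.107), with 12 of 20 alternatives passing and a range of 0.0226 to 0.133. Pdk1 did not pass without control 2, control 3, deleted 1, deleted 2 or deleted 3 (edgeR adjusted p = 0.149, 0.0833, 0.0712, 0.0650 and 0.106), with 9 of 20 alternatives passing and a range of 0.0304 to 0.217.

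Of 21 amino acid and one-carbon genes, 5 rose and 3 fell (6 and 7 adjusted over the list alone). Slc7a11, the cystine transporter, rose from 5.10 ± 0.591 to 18.1 ± 1.63 CPM (SD, n = 3 each), Sesn2 by 0.38, Trib3 by 0.37, Asns by 0.52 and Chac1 by 0.61, and Mthfd1l at −0.21, Slc1a5 at −0.15 and Shmt2 at −0.12 fell. No direction was called (camera adjusted p = 0.840, direction up, median −0.06, mean 0.15). Of 24 unfolded protein response genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Edem1 at 0.25, Ern1 at 0.25, Hspa5 at −0.13 and Canx at −0.11 (camera adjusted p = 0.977, direction up, median −0.01, mean 0.01). Without control 1 it had 0 members that fell. Of 18 heat shock and dissociation stress genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.537). These were Hmox1, haem oxygenase, at 1.73 ± 0.09, which is also on the macrophage list, Atf3, Bag3 at 1.21, Jun at −0.35 and Hspa8 at −0.14. Trib3 did not pass in DESeq2 (DESeq2 adjusted p = 0.0559), with 19 of 20 alternatives passing and a range of 6.7e-03 to 0.0559. Asns did not pass without control 2 or control 3 (edgeR adjusted p = 0.0672 and 0.0654), with 18 of 20 alternatives passing and a range of 1.9e-04 to 0.0672. Chac1 did not pass without control 2, deleted 2 or deleted 3 (edgeR adjusted p = 0.0702, 0.0516 and 0.104), with 15 of 18 alternatives passing and a range of 6.6e-03 to 0.104. Slc1a5 did not pass without control 2, deleted 1 or deleted 3 (edgeR adjusted p = 0.0855, 0.0582 and 0.0736), with 15 of 20 alternatives passing and a range of 1.0e-03 to 0.0855. Shmt2 did not pass without control 2, control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.0739, 0.0991, 0.0754 and 0.0649), with 13 of 20 alternatives passing and a range of 5.4e-03 to 0.0991. Ern1 did not pass without control 3 or deleted 1 (edgeR adjusted p = 0.0651 and 0.0608), with 17 of 20 alternatives passing and a range of 0.0122 to 0.0925. Hspa5 did not pass without control 1 or control 3 (edgeR adjusted p = 0.0507 and 0.0507), with 15 of 20 alternatives passing and a range of 2.0e-04 to 0.599. Canx did not pass without control 1, control 2, control 3 or deleted 3 (edgeR adjusted p = 0.0748, 0.0813, 0.0818 and 0.0771), with 11 of 20 alternatives passing and a range of 2.3e-03 to 0.721. Hspa8 did not pass without control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.0918, 0.0679 and 0.0992), with 14 of 20 alternatives passing and a range of 1.9e-03 to 0.118.

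Of 15 Notch pathway genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with the receptor gene Notch1 rising from 22.7 ± 0.165 to 52.0 ± 1.07 CPM (SD, n = 3 each) and Rbpj, the DNA-binding partner of Notch, by 0.42 ± 0.04. Camera called the list higher (adjusted p = 7.2e-07, but adjusted p = 0.0834 with an estimated correlation). Of 13 TGF-beta pathway genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone), with Ski, which restrains Smad proteins, at 0.69 ± 0.04 and the receptor gene Tgfbr1 at 0.61 ± 0.04 (camera adjusted p = 8.2e-04, but adjusted p = 0.0928 with an estimated correlation). Of 22 p53 targets, 8 rose and 1 fell (9 and 2 adjusted over the list alone), with Cdkn1a, Btg2, Trp53inp1 and Tnfrsf10b, at 0.81 ± 0.14, among the rises and Sesn1, at −0.17, as the fall (camera adjusted p = 4.6e-03, but adjusted p = 0.107 with an estimated correlation). Sesn1 did not pass without control 2, control 3, deleted 1, deleted 2 or deleted 3 (edgeR adjusted p = 0.0877, 0.102, 0.0565, 0.0515 and 0.108), with 15 of 20 alternatives passing and a range of 2.2e-03 to 0.108.

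Of 32 interferon-stimulated genes, 12 rose and 3 fell (16 and 3 adjusted over the list alone), with Stat1 rising from 198 ± 3.76 to 273 ± 9.01 CPM (SD, n = 3 each) and Rsad2, an antiviral enzyme, by 1.51 ± 0.21. The falls were Gbp3 at −0.24, Irgm1 at −0.23 and Ifi47 at −0.24, which encode interferon-inducible GTPases, and 8 of the 15 changed members lay below 10 CPM. Camera called the list higher (adjusted p = 6.7e-03, but adjusted p = 0.309 with an estimated correlation), and not among genes of at least 5 CPM, nor of at least 10 CPM without control 1 (camera adjusted p = 0.0669 and 0.430, range 1.2e-04 to 0.430). Of 17 MHC class II presentation genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone), namely Ifi30, a lysosomal reductase, at 0.31, H2-Eb2 at 0.24, H2-Ob at 0.20, H2-Eb1 at 0.16 and Ciita at 0.19. They were called higher (camera adjusted p = 0.0352, but adjusted p = 0.504 with an estimated correlation), and not without control 1, control 2 or deleted 2 (camera adjusted p = 0.225, 0.0539 and 0.0502, range 2.8e-03 to 0.504). In the same libraries as these interferon-stimulated and MHC class II genes, the dendritic cell and macrophage lists had medians of 0.82 and 1.53. None of the 5 changed MHC class II members stands on a list of another cell type, which does not show in which cells they rose. Of 21 MHC class I presentation genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.504, range 0.0242 to 0.964). They were H2-T23 at 0.23, Nlrc5 at 0.29, Psmb9 at 0.20, Tapbp at 0.12, Tap1 at 0.11 and, lower, Canx at −0.11, and without control 1 the counts were 3 and 2. H2-Eb1 did not pass without control 1 or control 2 (edgeR adjusted p = 0.0507 and 0.0634), with 18 of 20 alternatives passing and a range of 2.5e-04 to 0.0634. Ciita did not pass without control 3, deleted 1 or deleted 3 (edgeR adjusted p = 0.0651, 0.0599 and 0.0835), with 17 of 20 alternatives passing and a range of 7.2e-04 to 0.0835. Psmb9 did not pass without control 2, deleted 2 or deleted 3 (edgeR adjusted p = 0.102, 0.0599 and 0.0662), with 16 of 20 alternatives passing and a range of 0.0142 to 0.102. Tapbp did not pass without control 1, control 2, control 3, deleted 2 or deleted 3 (edgeR adjusted p = 0.0887, 0.10, 0.0723, 0.0755 and 0.109), with 13 of 20 alternatives passing and a range of 0.0146 to 0.109. Tap1 did not pass without control 1, control 2, control 3, deleted 2 or deleted 3 (edgeR adjusted p = 0.141, 0.112, 0.0849, 0.0887 and 0.158), with 11 of 20 alternatives passing and a range of 0.0174 to 0.158. Canx did not pass without control 1, control 2, control 3 or deleted 3 (edgeR adjusted p = 0.0748, 0.0813, 0.0818 and 0.0771), with 11 of 20 alternatives passing and a range of 2.3e-03 to 0.721.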

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

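The alternatives limma on log2(CPM + 1) without further scaling, RLE factors, library totals alone, control 1 left out among genes of at least 10 CPM, the count without members of other-cell-type and sex-linked lists, the NF-kB subunits and regulators without Nfkb2, and the size threshold on the log2 fold were chosen after the data were seen. Leaving out each library in turn was counted apart from the other settings. Among the named genes, 2905 values in the other settings had the direction and side of the threshold reported, 98 lost the call, 11 gained it and 1 reversed. Leaving out each library in turn gave 1202, 126, 4 and 0. For the lists these numbers were 568, 43, 21 and 2, and 245, 9, 4 and 0 with each library left out in turn. The other settings include control 1 left out among genes of at least 10 CPM. That setting gave 152 of the 2905 and 15 of the 98 for genes, and 29 of the 568 and 7 of the 43 for lists. With quantile normalization in limma with 1 CPM added, Ncl was at 0.024 (limma adjusted p = 0.76) and the NF-kB subunits and regulators turned up (camera adjusted p = 0.366), and the cause was not tested. The same list turned up with Nfkb2 left out of it (camera adjusted p = 0.819).

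Genes changed numbered 1629 with DESeq2, 1639 with no filter, 1792 at 5 CPM or more, 1750 with the replicate block, 2048 with quantile normalization in limma with 1 CPM added and 2053 without members of other-cell-type and sex-linked lists. The last count drops only genes on those lists. It does not show how many changes come from other cells or from sex. Leaving out 1 library gave 1228 to 2335 changed genes, 825 to 1489 higher, 403 to 846 lower and 10 to 30 lower with a log2 fold of at least 1, where fewer samples remain.

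Genes lower with a log2 fold of at least 1 numbered 9 with no low-count filter, 10 at a mean of at least 5 CPM, 6 in limma with 1 CPM added, 8 with 0.5 CPM added and 5 at 10 CPM or more without control 1. Those higher by as much numbered 78 at 5 CPM or more, 122 in limma with 1 CPM added, 192 with 0.5 CPM added and 47 at 10 CPM or more without control 1. Median centring and quantile normalization were run only in limma with 1 CPM added: beside its 6 lower and 122 higher, median centring gave 6 and 115, and quantile normalization 8 and 93. Median centring also gave 1197 higher and 1059 lower of any size, where limma with 1 CPM added alone gave 1317 and 839. A larger pseudocount shrinks folds of low counts and a filter removes such genes by construction. At 10 CPM or more without control 1, where fewer genes and samples remain, 542 genes were lower and 11 lists higher. With an estimated correlation, camera placed 7 lists higher and 2 lower. Control 2, control 3 and deleted 3 moved the number lower most, to 418, 528 and 403. Differences of 1.5-fold were recovered in 73.1% of simulated genes at this depth.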

Other observations

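All tests of the 3 patterns weighed here were chosen after the result was seen, and the counts over other splits of the libraries were planned. Among genes of at least 50 CPM on no list, also chosen after their values were seen, the largest rises were in Hivep3, a zinc finger protein gene, from 32.9 ± 2.64 to 74.0 ± 9.96 CPM, the calcium channel gene Cacna1e from 53.8 ± 3.39 to 112 ± 14.1 CPM and Treml2 from 36.0 ± 1.07 to 74.0 ± 0.603 CPM (SD, n = 3 each). Gp49a, with reads it can share with its paralog Lilrb4, rose by 0.90 ± 0.05, Fscn1, which bundles actin, by 0.87 ± 0.08 and Lrmp by 0.70 ± 0.04. After Mid1, described above, the largest falls were in Setbp1 from 69.9 ± 5.72 to 44.5 ± 4.29 CPM, Ticam2, an adaptor of Toll-like receptor signalling, from 101 ± 4.62 to 65.5 ± 1.23 CPM and Grm6, a glutamate receptor gene, from 65.6 ± 4.68 to 43.6 ± 1.99 CPM (SD, n = 3 each). Gpr174, a G protein-coupled receptor gene, changed by −0.56 ± 0.04, St8sia6, a sialyltransferase gene, by −0.55 ± 0.05 and Rasgef1b by −0.53 ± 0.04. The highest adjusted p of these 12 genes was 2.6e-04 (edgeR, Benjamini-Hochberg).

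Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes, with 2111 against at most 0 elsewhere. For lists called it was also 1 of 10, with 29 against at most 19 elsewhere. These 10 splits are too few for a share under 0.05. In splits that mix the groups, the difference between the groups adds to the spread within each side. Their counts of genes and lists are thus no measure of false calls.

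Y-linked genes summed to 227 CPM on average in the Nfkb2-deleted libraries and Xist was at 56.1% of the control mean. A library swapped between the groups is argued against, since no control exceeded 2.04 CPM of Y-linked transcripts. That each Nfkb2-deleted library held cells of both sexes is a candidate explanation, with Xist at 56.1% beside the Y-linked transcripts. Whether the Nfkb2-deleted libraries were drawn from one pool of cells stays open, with a CV over them of 3.55% for the Y-linked sum and of 11.8% for Xist. The groups differ in sex as they do in Nfkb2, and an effect of Nfkb2 on Xist was not tested.

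Markers of other blood cells rose in the Nfkb2-deleted libraries, with Lyz2 at 68.7 CPM. Fewer B cells with every other type raised alike stays open. The median of the macrophage list exceeded that of the T cell list by 1.09 on the log2 scale (permutation p = 1e-04 over 100000 resamples, two-sided). This cannot decide it, because a marker's fold depends on its level in the controls and genes are not independent replicates. Among the tested lists of other cell types, the pair had the highest and lowest medians, 1.53 and 0.44. The stromal list, with 3 measured members and too small for camera, had a median of −0.11. The erythroid, neutrophil, NK, platelet and dendritic cell lists had medians of 1.37, 1.35, 1.16, 0.85 and 0.82. More macrophages or monocytes may account for part of the rise. That 73.3% of their markers rose is the pattern itself and cannot decide between this and other explanations. Of these 15 markers, 4 stand on another list and 3 were at 10 CPM or more in the controls. The cells had been purified with beads, but how pure they were was not measured here. Genes switched on inside B cells lacking Nfkb2 stay open, because bulk libraries do not separate cells and the median of the follicular list, 0.021, had members going both ways.

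Control 1 held nervous tissue transcripts, with 26 of 32 textbook markers of neurons and glia (81.2%) at 10 times or more the level of any other library. RNA or reads from nervous tissue in this library is a candidate explanation, with Snap25, the most abundant of these 26, at 953 counts. Mbp, a myelin gene, had 2803 counts here and up to 3431 elsewhere. Whether such reads came with the cells, or were reads of another multiplexed library assigned to this one, cannot be told apart without the other libraries of the run; all 714 genes at 10 times or more, of nervous tissue or not, held 0.276% of its counts. No biological explanation of these transcripts in control 1 was tested.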
